A study of Mus musculus with 4 samples.

How the data were processed

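Total RNA was depleted of ribosomal RNA and sequenced. Per the submitters' processing notes, read quality was examined with FastQC, reads were aligned to the mouse genome build mm10 with STAR, counts per gene were made with HTSeq, and DESeq2 was used for normalization. The notes give no versions, and the annotation release and the strand setting are not given in the sources used here. The authors' table of counts and their table of normalized values were used. The normalized values equal log2 of the count divided by a size factor, plus 1, and those size factors equal the ones DESeq2 gives for these counts (1.15, 1.02, 1.04 and 0.832 in the order TRF1ΔN at 0 h and 24 h, Vp16-TRF1ΔN at 0 h and 24 h).

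The count table held 21971 genes and 4 rows for the constructs, named TRF1DN, VP16, Vec_part1 and Vec_part2, and every gene in it had at least 2 counts in total. The construct rows took 0.0372%, 0.0582%, 0.0136% and 0.0129% of the counts in that order of libraries (exact 95% binomial intervals at most 0.00144 percentage points wide) and were kept out of library sizes and tests. A symbol from GENCODE was found for 21889 genes. Libraries were scaled with edgeR's TMM factors, and values are CPM of the scaled library. A count of 3 equals 0.0630, 0.0713, 0.0696 and 0.0875 CPM in the 4 libraries and served as the floor for a count of 0. Intervals and floors cover counting error only.

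With 1 library per group, an additive model with a term for the line and a term for TGFβ was fitted with edgeR's quasi-likelihood method to the 14305 genes that passed filterByExpr. Its 1 residual degree of freedom is the departure from additivity, and the fit had a prior degrees of freedom of 3.39 and a biological coefficient of variation of 0.0931. Tests were two-sided, p was adjusted by Benjamini and Hochberg's method, and genes with an adjusted p under 0.05 were called. The SE given after ± is the size of the log2 change divided by the square root of the test's F statistic. It draws on the spread across genes, so a gene's ratios in the 2 lines can lie further apart than it implies. The TGFβ response within a line, the difference between lines at a time and the difference between the responses have no test. They are given as log2 ratios with a prior count of 2, and genes are counted when the ratio is at least 2-fold, the mean at least 1 CPM (11777 genes) and the 95% counting interval excludes a ratio of 1. The interval is exact and conditional on the sum of the counts (Clopper-Pearson) for a pair, and rests on Poisson variances for the difference of responses.

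The genes named were chosen by a rule: among genes with a mean of at least 5 CPM, the 10 largest called changes in each direction that were at least 2-fold in both lines, or, for a comparison without calls, the 10 in each direction with the largest smaller ratio of the pairs. For untested comparisons the 5 largest counted in each direction were named, and some genes were named whatever their values: Terf1, Cdh1, Epcam, Cdh2, Vim, Fn1, Smad7, Snai1, Snai2, Zeb1, Zeb2, Id1 and Esrp1. Predicted genes, pseudogenes, small nucleolar RNA and mitochondrial genes were left out of these ranked picks. Examples from lists are up to 2 members with the highest and 2 with the lowest values, and members that moved against their list's name were added after their values were seen. Results for some genes that the rule picks are not reported here. The size of attenuation was taken as the difference of responses signed by the direction of the average response. Comparisons, lists, the naming rule and most alternatives were set before the data were examined.

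The lists cover epithelial and junction genes, mesenchymal and matrix genes, actin and contractile genes, EMT transcription factors, TGFβ and SMAD targets, BMP and Id targets, shelterin and telomere genes, Polycomb, Hox genes, p53 targets, proliferation, interferon response, inflammatory NF-κB targets, endoplasmic reticulum stress and ATF4, cholesterol synthesis, glycolysis and hypoxia, Notch, Wnt targets, mitochondrially encoded genes, and markers of luminal, basal, immune, endothelial, fibroblast and adipocyte cells. They were written from general knowledge, not from these libraries. A list's value is the median log2 ratio of its members with a mean of at least 1 CPM, set against 10000 random lists drawn from 20 bins of expression. Members of a list can move together, whereas random lists are drawn gene by gene, so percentiles may overstate how unusual a list is. Genes near distal chromosome ends were found from GENCODE coordinates for GRCm38 (the same build as mm10), for 21865 genes on 20 chromosomes, with the end of the last annotated gene taken as the chromosome's end.

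In a self-test on simulated counts with the same depth, 88 of 100 genes with a true 2-fold TGFβ change and 99 of 100 with a 4-fold change were called, with 5 false calls among 192. For the line term 87 of 100 and 100 of 100 were called, with 4 false among 191. These simulated effects were additive and touched few genes, so the test does not show the error rate where the lines respond differently. The pair interval covered the true ratio for 95.4% of 11782 genes and the interval of the difference of responses for 95.1%. Those counts were drawn with Poisson spread, which the intervals assume, so this checks the calculation and not the coverage in real libraries.

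Alternatives were DESeq2's size factors, no filter on low counts, a mean of at least 5 CPM, a prior count of 0.5, DESeq2's Wald test, limma-voom, limma on the authors' normalized log2 values, other distances from chromosome ends, and leaving out each library in turn. Leaving out mitochondrially encoded genes, and thinning the counts to equal depth, were chosen after seeing the data. The raw reads and the genome sequence were not used here, so RNA of telomeric repeats was not measured. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.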

Results

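NMuMG cells, an epithelial line from normal mouse mammary gland that undergoes epithelial-to-mesenchymal transition (EMT) when given TGFβ, were profiled by RNA-seq in 4 libraries. The cells stably expressed a mutated human TRF1 (TRF1ΔN), a telomere-binding protein, or the same protein fused to Vp16 (Vp16-TRF1ΔN), a viral transcription activation domain. Per the series description, the fusion raises RNA of the TERRA type, the noncoding RNA transcribed from telomeres, and the question was how this alters the EMT expression signature. Each line was sampled before (0 h) and after 24 h of TGFβ at 5 ng/ml, so each of the 4 groups held 1 library and no group had replicates. The libraries held 46001039 counts (TRF1ΔN, 0 h), 43379387 counts (TRF1ΔN, 24 h), 41958849 counts (Vp16-TRF1ΔN, 0 h) and 35423556 counts (Vp16-TRF1ΔN, 24 h), and 20047, 19960, 19849 and 19411 genes had at least 1 count. The rows analysed were genes and 4 construct rows, so RNA of the telomeric repeats themselves was not measured here.

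The construct rows separated the lines as their labels name them. The row named VP16 had 0 counts and 1 count in the TRF1ΔN libraries at 0 h and 24 h, and 15 and 27 counts in the Vp16-TRF1ΔN libraries. A count of 0 allows up to 0.0630 CPM in the TRF1ΔN library at 0 h, against 0.348 CPM (counts scaled to library size) in the Vp16-TRF1ΔN library at 0 h. At 24 h VP16 was 33.2-fold higher in the Vp16-TRF1ΔN line, with a 95% counting interval of 5.47 to 1358 that reflects the single count in the other library. The row named TRF1DN was much less abundant in the Vp16-TRF1ΔN line: 2.85 CPM against 39.1 CPM at 0 h, 13.7-fold lower (interval 11.4 to 16.6), and 4.64 CPM against 185 CPM at 24 h, 39.9-fold lower (34.1 to 47.0). Within the TRF1ΔN line, TRF1DN was 4.74-fold higher after TGFβ (4.503 to 4.99), and within the Vp16-TRF1ΔN line it was 1.63-fold higher (1.28 to 2.07). The mouse gene Terf1, which encodes endogenous TRF1, fell with TGFβ (log2 change -0.44 ± 0.09 SE, adjusted p = 0.0180, edgeR quasi-likelihood test), a call that DESeq2's Wald test did not make (adjusted p = 0.0877), and was alike in the lines, with a ratio of 1.04 at 0 h (0.947 to 1.15) and 0.963 at 24 h (0.852 to 1.09).

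**Figure D1:**
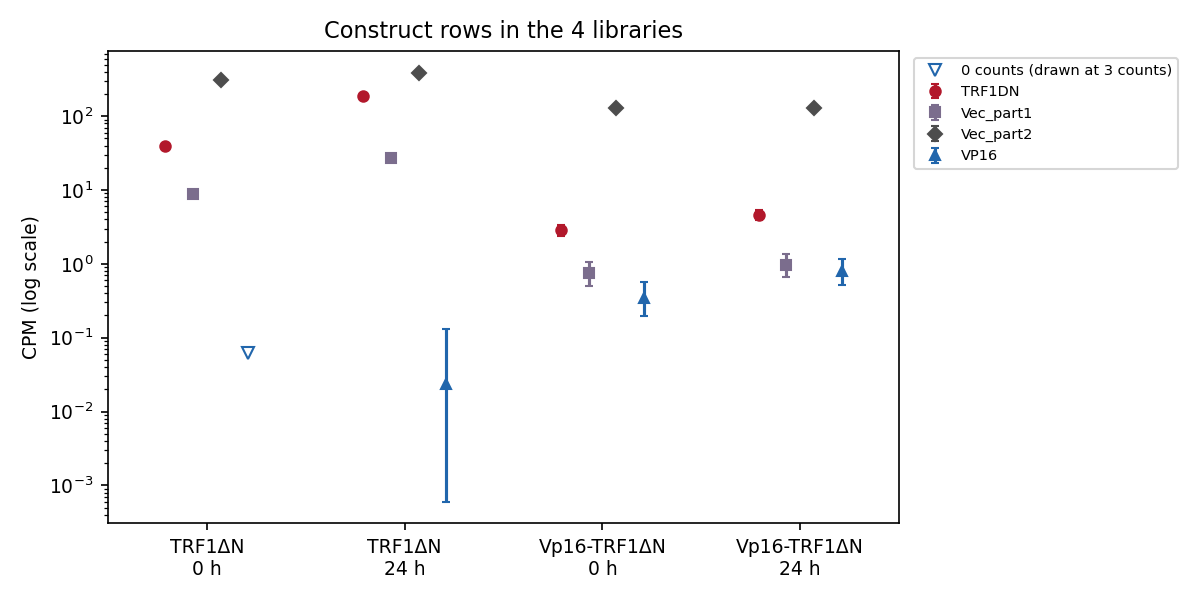
CPM (log axis) of the 4 construct rows in each library, with 95% Poisson intervals; an open triangle marks 0 counts, drawn at the level of 3 counts. TRF1DN stands at 39.1 and 185 CPM in the TRF1ΔN libraries and at 2.85 and 4.64 CPM in the Vp16-TRF1ΔN libraries.

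The expression of a large part of the genes differed between 0 h and 24 h of TGFβ in both lines. The labels name no 24 h library without TGFβ, so an effect of time in culture cannot be told apart from one of TGFβ. Matrix genes and a cytokine gene were among those that rose most, named by size and not tested as groups. Has2, a hyaluronan synthase, rose by 9.78 ± 0.40 (SE) on the log2 scale, from 4 to 7101 counts in the TRF1ΔN line and 6 to 1098 in the Vp16-TRF1ΔN line. Its log2 ratios in the respective lines were 10.32 and 7.42, further apart than this SE implies. Col5a3, a type V collagen chain, rose by 8.05 ± 0.28, the cytokine gene Il11 by 7.56 ± 0.34, the matrix glycoprotein gene Tnc by 7.40 ± 0.16 and the protease gene Ctsw by 7.23 ± 0.18. Among the genes that fell most were Mx1, an interferon-induced GTPase (-6.67 ± 0.18), Eps8l3 (-6.67 ± 0.28), Clrn3 (-6.61 ± 0.24), the keratin gene Krt6a (-6.27 ± 0.13) and Cbln3 (-6.26 ± 0.28). Adjusted p of these 10 genes lay at 0.000858 to 0.000914 (edgeR quasi-likelihood test, Benjamini-Hochberg). By the rule that picked them, each was called and at least 2-fold changed the same way in both lines.

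The other 10 genes named, likewise the largest changes at a mean of 5 CPM or more, had 3 or fewer counts in some library, so ratios are given per line with 95% counting intervals. Nat8l, the N-acetylaspartate synthase gene, went from 0 to 982 counts in the TRF1ΔN line, at least 370-fold higher against a floor of 3 counts, and from 0 to 130 counts in the Vp16-TRF1ΔN line, at least 54.5-fold higher. Tnfaip6, which encodes a hyaluronan-binding protein, was 236-fold higher in the TRF1ΔN line (91.9 to 869) and at least 65.0-fold higher in the Vp16-TRF1ΔN line. Chrna1, an acetylcholine receptor subunit gene, was 394-fold higher (134 to 1913) and 502-fold higher (89.6 to 19871) in the respective lines. Kif26b, of the kinesin family, was 314-fold higher (107 to 1523) and 82.4-fold higher (31.8 to 305), and Tmeff1 183-fold higher (71.2 to 674) and 108-fold higher (29.3 to 895). In the other direction, the albumin gene Alb was 245-fold lower (83.7 to 1192) and 102-fold lower (62.8 to 179). Sptssb, a subunit of serine palmitoyltransferase, was 492-fold lower (168 to 2386) and 73.9-fold lower (50.7 to 112), and Smim6 at least 169-fold lower and 64.1-fold lower (32.3 to 149). Dio3, the deiodinase that inactivates thyroid hormone, went from 1434 counts to 1 and from 1243 to 32, which is 30.9-fold lower (21.8 to 45.4) in the Vp16-TRF1ΔN line. Gjb1, which encodes a gap junction connexin, was 155-fold lower (52.8 to 755) and 37.5-fold lower (21.3 to 73.0). All 10 genes passed the test of the average response, as the naming rule requires, with adjusted p of 0.000858 to 0.00361 (edgeR quasi-likelihood test).

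Several classical EMT markers passed the test. E-cadherin (Cdh1), the adhesion molecule of epithelial junctions, fell by 1.46 ± 0.16 on the log2 scale (adjusted p = 0.00398), from 366 to 107 CPM in the TRF1ΔN line and from 368 to 166 CPM in the Vp16-TRF1ΔN line. N-cadherin (Cdh2) rose by 1.31 ± 0.07 (adjusted p = 0.00100) and fibronectin (Fn1) by 3.501 ± 0.11 (adjusted p = 0.000858). The EMT transcription factor genes Snai1 (3.67 ± 0.41), Snai2 (1.74 ± 0.23), Zeb1 (1.95 ± 0.08) and Zeb2 (1.71 ± 0.07) rose, as did Smad7 (1.37 ± 0.14), an inhibitor of TGFβ receptor signalling. Adjusted p of these 5 genes lay between 0.000858 and 0.00548 in edgeR's quasi-likelihood test. Id1, a target of BMP signalling, fell by 2.22 ± 0.13 (adjusted p = 0.00121). Vimentin (Vim) was already at 3210 CPM in the untreated TRF1ΔN library and did not pass the test (0.16 ± 0.08, adjusted p = 0.147). Epcam had 18, 11, 4 and 4 counts and did not pass (adjusted p = 0.637), and Esrp1, a splicing regulator of epithelial cells, had at most 3 counts in any library and was not tested.

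**Figure D2:**
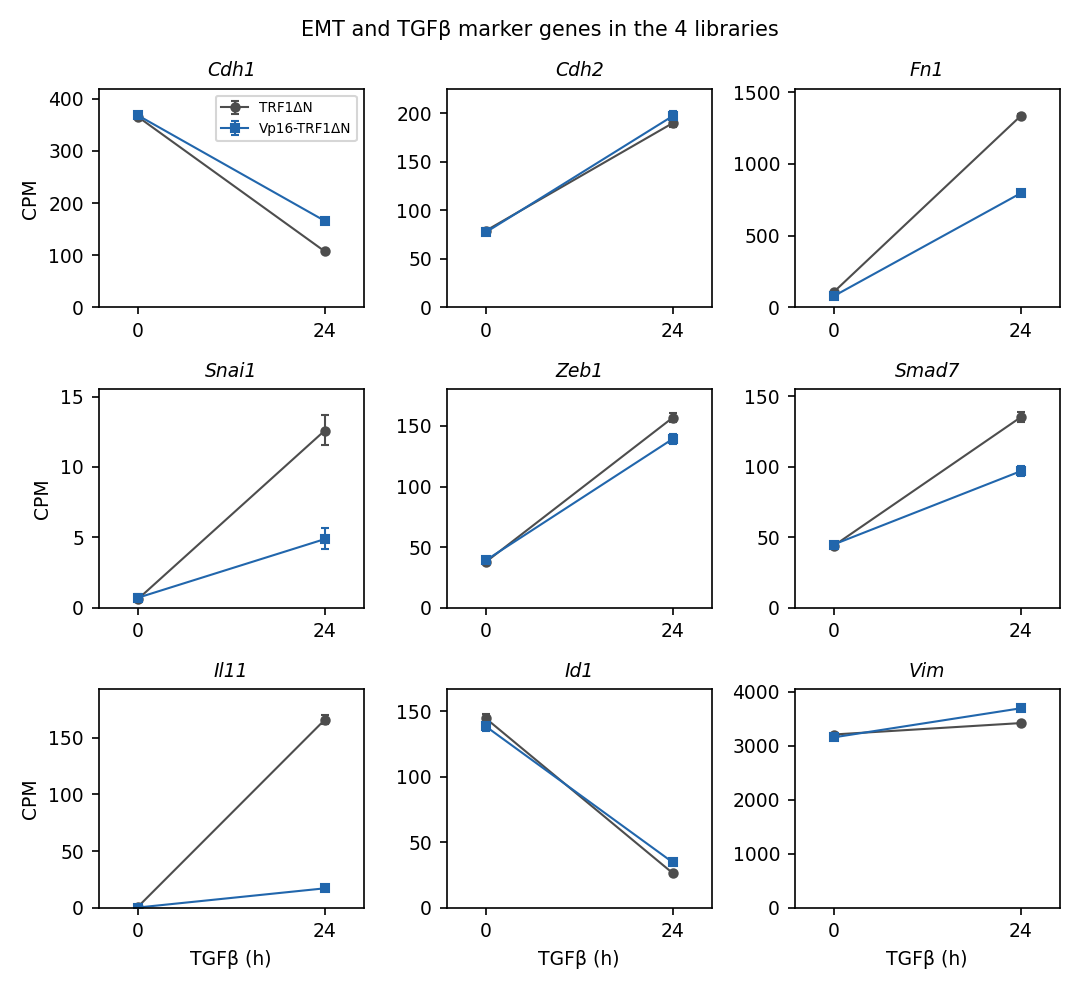
CPM against hours of TGFβ for 9 marker genes, with 1 library per point, circles for the TRF1ΔN line, squares for the Vp16-TRF1ΔN line and 95% Poisson intervals of the counts. Cdh1 ends at 107 CPM in the TRF1ΔN line and at 166 CPM in the Vp16-TRF1ΔN line, while Fn1 ends at 1334 and 795 CPM.

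The average TGFβ response was tested over both lines in an additive edgeR quasi-likelihood fit, in which any difference between the lines' responses counts as noise and the spread rests on 1 residual degree of freedom. Of 14305 genes tested, 3305 rose and 3631 fell, together 48.5% of them, and 1232 and 1493 of these changed at least 2-fold. The labels do not say whether libraries came from separate cultures, so adjusted p measures only the spread among these 4 libraries.

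Lists of EMT genes were compared first. In the list of mesenchymal and matrix genes 26 of 33 measured members rose, 2 fell and 5 did not pass (26 and 2 adjusted over the list alone), with a median log2 ratio of 1.56, above all 10000 random lists matched on expression. Tnc (7.40) and Thbs1, thrombospondin 1 (5.41), rose, and Pdgfrb went from 0 to 217 counts and from 1 to 36 counts in the respective lines. S100a4 (-1.44) and Plaur (-0.62), both of which are used as mesenchymal markers, fell. In the list of actin and contractile genes 19 of 23 rose and 2 fell (19 and 2 adjusted over the list alone), with Zyx (2.67) and Ccn1 (2.365) highest, and Ezr (-1.47), which links actin to the membrane of epithelial cells, and Lmo7 (-1.19) lowest. Of 22 EMT transcription factor genes 15 rose, 4 fell and 3 did not pass (16 and 4 adjusted over the list alone): Snai1 (3.67) and Fosl2 (2.31) were highest, Twist2 (-1.33) and Fosl1 (-1.08) lowest.

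Of 33 targets of TGFβ and SMAD signalling 26 rose, 2 fell and 5 did not pass (27 and 2 adjusted over the list alone), with a median of 1.37, above all random lists. Il11 (7.56) and Wnt9a (6.13) rose most. Those that fell were Dab2 (-0.60, not called by DESeq2's Wald test) and Cdkn1a (-0.56), the gene of the cell cycle inhibitor p21. Of 9 BMP and Id targets 6 fell and 1 rose (6 and 1 adjusted over the list alone): Id2 (-2.499) and Id1 (-2.22) were lowest, and the homeobox gene Dlx3 rose by 1.37. In the list of epithelial and junction genes 17 of 28 fell, 6 rose and 5 did not pass (18 and 6 adjusted over the list alone), with a median of -0.71, below all random lists. Krt19 (-3.42) and Muc1 (-3.37) fell most. Some members of this list rose: Krt18 (0.56), Krt8 (0.30), Jup (0.55), F11r (0.55) and Pkp2 (0.51), and Cldn4, a tight junction claudin, went from 1 to 563 counts and from 1 to 152 counts. Every one of the 40 measured proliferation genes fell (40 adjusted over the list alone), with a median of -1.52, led by the replication genes Cdc6 (-2.64) and Tk1 (-2.46) and least for the mitotic genes Cenpe (-0.85) and Cenpf (-0.98).

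Of 25 cholesterol synthesis genes 15 fell with TGFβ and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.41 and Insig1 (0.28, not called by DESeq2's Wald test) the riser. Of 26 genes of glycolysis and hypoxia 15 fell and 9 rose (15 and 9 adjusted over the list alone), among them Egln3 (-2.79), Ldha (-1.66), Pfkfb4 (3.39) and Hk2 (1.59). Of 28 genes of endoplasmic reticulum stress and ATF4, 13 fell and 7 rose (14 and 8 adjusted over the list alone), from Slc7a11 (-3.68) and Cth (-2.66) to Nupr1 (1.83) and Atf3 (1.82). Of 30 p53 targets 12 fell and 4 rose (12 and 4 adjusted over the list alone), with Ephx1 (-1.96) and Gtse1 (-1.39) lowest and Gadd45a (3.85) and Pmaip1 (1.04) highest. Of 21 interferon response genes 8 rose and 4 fell (8 and 4 adjusted over the list alone), between Mx1 (-6.67) and Oasl2 (2.60). Of 24 inflammatory NF-κB targets 7 rose and 8 fell (7 and 9 adjusted over the list alone), between Saa3 (-3.01) and Ptgs2 (2.58). Of 11 Notch genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), with the ligand gene Jag1 at 2.79, Notch4 at 3.09 and Notch1 at -2.85. Of 11 Wnt targets 4 rose and 3 fell (5 and 3 adjusted over the list alone), between Wnt4 (-2.02) and Tcf7 (1.496).

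Genes of telomere maintenance and of Polycomb complexes went both ways. Of 32 shelterin and telomere genes 12 fell and 6 rose (12 and 6 adjusted over the list alone), with a median of -0.15, at percentile 9.86 of the random lists. The helicase genes Blm (-1.19) and Rtel1 (-0.96) were lowest and Tep1 (0.77) and the tankyrase gene Tnks (0.67) highest. Of 24 Polycomb genes 7 fell and 5 rose (7 and 5 adjusted over the list alone), from Cbx7 (-1.24) and Epop (-1.08) to Kdm6b (1.31) and Jarid2 (0.88). None of the 4 measured Hox genes passed the test (0 and 0 adjusted over the list alone), among them Hoxa3 (0.35), Hoxa5 (0.13) and Hoxa7 (-0.29).

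Mitochondrial RNA moved with the treatment. Of 9 mitochondrially encoded genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.51. The mitochondrial ribosomal RNA mt-Rnr2 took 9.02% and 11.8% of the counts in the TRF1ΔN line at 0 h and 24 h, and 10.1% and 13.9% in the Vp16-TRF1ΔN line, each with an exact 95% binomial interval less than 0.0228 percentage points wide. With all mitochondrially encoded genes left out before normalization, including those outside this list, 3226 of 14290 genes tested rose and 3830 fell with TGFβ. This setting was added after the data were seen.

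Markers of other cell types were measured too. Of 7 measured basal mammary genes 4 fell and 2 rose (4 and 2 adjusted over the list alone), between Krt6a (-6.27) and Col17a1 (4.47). Of 4 luminal genes 2 fell, Cd14 (-1.89) and Areg (-1.28), and 1 rose, Gata3 (1.65), with 2 and 1 adjusted over the list alone. The lists for immune, endothelial, fibroblast and adipocyte cells had 1, 2, 2 and 1 members at a mean of 1 CPM or more, too few for a median: Cd68 at 3.09 CPM, Flt1 and Egfl7 at 77.0 and 2.78 CPM, Gsn and Pdgfra at 385 and 1.55 CPM and Pparg at 20.1 CPM. The leukocyte antigen gene Ptprc had at most 7 counts in a library, the endothelial gene Pecam1 at most 3 and the adipocyte gene Adipoq at most 1. Other members below 1 CPM moved with TGFβ. In the TRF1ΔN and Vp16-TRF1ΔN lines, Csf1r went from 1 to 101 and from 2 to 21 counts, and Cdh5 from 4 to 50 and from 5 to 24. Lyz2 went the other way, from 10 to 0 and from 9 to 0, as did Cd36, from 23 to 2 and from 21 to 1.

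The TGFβ response was then set out for each line separately, with no test, since each group had 1 library. A gene was counted when its ratio was at least 2-fold, its mean at least 1 CPM and the 95% counting interval of its ratio excluded 1, and genes are named from those with a mean of 5 CPM or more. In the TRF1ΔN line 989 of 11777 genes were counted as higher and 1285 as lower after TGFβ, with Has2 (10.32 on the log2 scale), Nat8l, Col5a3 (8.56), Il11 (7.89) and Chrna1 largest upward, and Dio3, Sptssb, Smim6, Alb and Kif12 downward; Kif12, of the kinesin family, stood at -7.28. In the Vp16-TRF1ΔN line 815 were counted as higher and 1071 as lower, with Has2 (7.42), Chrna1, Col5a3 (7.34) and Tnc (6.87) among the largest upward, and Alb, Krt6a (-6.26), Mx1 (-6.26), Sptssb and Clrn3 (-6.07) downward. The 2 lines shared 729 of the genes counted as higher, where independent lists would share 68.4, and 962 of those counted as lower, where independent lists would share 117. No gene was counted in opposite directions. Across the 11777 genes, which are not independent replicates, the 2 responses had Pearson's r of 0.949 and Spearman's rho of 0.919, and the pairs of libraries behind them share no library.

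Fewer genes differed between the lines before treatment than after it. At 0 h, 21 genes were counted as higher and 49 as lower in the Vp16-TRF1ΔN line. The 3 higher genes with a mean of 5 CPM or more were the liver-type secreted protein genes Alb (log2 ratio 1.45), Itih2 (1.33) and C4bp (1.06). Among the lowest at that level of expression were the alkaline phosphatase gene Alpl (-2.92), Lrrc32, which encodes a cell surface protein that holds latent TGFβ (-2.92), the iron-binding lipocalin gene Lcn2 (-2.44) and the intermediate filament gene Nes (-2.11). After 24 h of TGFβ 249 genes were counted as higher and 139 as lower, a balance that turned without a filter on low counts (417 higher, 483 lower). Akr1c19, an aldo-keto reductase gene (3.54), AW112010 (2.90), Dio3 (32 counts against 1), Ranbp3l (22 against 1) and Sptssb (27 against 3) were highest among genes with a mean of 5 CPM or more. Il11 (-3.27), Alpl (-2.74), Has2 (-2.39), Nes (-2.26) and Nat8l, 6.15-fold lower (5.12 to 7.44), were lowest. Of the genes counted at 0 h, 7 of the higher and 27 of the lower were counted in the same direction at 24 h, where independent lists would share 0.444 and 0.578.

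Averaged over 0 h and 24 h, the lines were compared in the same additive fit. Gene values in brackets below are on the log2 scale unless marked as a fold. They are this average unless a time is named. No gene of 14305 passed the edgeR quasi-likelihood test, and the smallest adjusted p was 0.0837, shared by Alpl (-2.85 ± 0.12), Nes (-2.21 ± 0.10) and Timp3, a tissue inhibitor of metalloproteinases (-1.63 ± 0.08). Before adjustment 1779 genes passed. With DESeq2's Wald test 13 genes were called higher and 34 lower, whereas limma-voom, and limma on the authors' normalized values, called 0. In a comparison without calls, genes were ranked by the smaller of their ratios at 0 h and 24 h. The first upward were Alb (2.73-fold at 0 h, interval 2.52 to 2.96), Itih2 (1.504), C4bp (1.40), C1s1 (1.28), Ms4a4b (1.07), Slc17a4 (1.03), Dbp (1.014), Cpq (0.97), Rpph1 (0.81) and Sptssb (1.66-fold at 0 h, 1.56 to 1.77), all higher in the Vp16-TRF1ΔN line. Those lower there were Alpl, Nes, Timp3, Il11 (-1.20 at 0 h, from 11 counts against 31, and -3.27 at 24 h), Lcn2 (-2.13), Lrrc32 (-2.04), Tnc (-1.87), Eda2r (-1.84) and Smoc2 (-1.54), and Tnfaip6, with 155 counts against 835 at 24 h. None of these 20 passed the test (adjusted p of 0.0837 to 0.399, edgeR), while DESeq2's Wald test called 14 of them. Alpl, Nes and Timp3 passed in edgeR with mitochondrially encoded genes left out (adjusted p of 0.0313, 0.0313 and 0.0344), a setting chosen after seeing the data.

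No list had a member passing the line test over all genes. Adjusted over the list alone, 1 mesenchymal and matrix gene was higher and 8 were lower in the Vp16-TRF1ΔN line. Also lower were 5 cholesterol synthesis genes, 3 NF-κB targets, 2 TGFβ and SMAD targets, 1 p53 target and 1 basal gene, and the other lists had 0. The median of the NF-κB targets was nonetheless 0.09, at percentile 99.4, with 14 members above 0 and 10 below. The lists with medians below all random lists were TGFβ and SMAD targets (-0.21), actin and contractile genes (-0.19), proliferation genes (-0.34) and cholesterol synthesis genes (-0.17). Random lists were matched on expression and not on GC content. Across genes, line ratios fell with GC content (Spearman's rho of -0.189 for this average, -0.145 at 0 h and -0.182 at 24 h). A part played by GC content in these medians was not tested. The 9 BMP and Id targets had a median of 0.34, at percentile 99.99. Shelterin and telomere genes had a median of -0.08 at percentile 3.47 and Polycomb genes of -0.02 at percentile 36.7. These values average 0 h and 24 h. TGFβ and SMAD targets had a median of -0.05 at 0 h (bootstrap interval -0.13 to 0.03, percentile 5.2) and -0.43 at 24 h. BMP and Id targets had 0.07 at 0 h (-0.27 to 0.35) and 0.50 at 24 h. For both lists the average thus rests mostly on 24 h, with no clear difference before TGFβ. Actin and contractile (-0.14), proliferation (-0.15) and cholesterol synthesis genes (-0.19) lay below all random lists at 0 h too. There 1 library was compared with 1, and members of a list can move together, so these placings may overstate the difference between lines. Each line is represented by 2 libraries, and the labels name no independent clones.

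The stated aim concerns the change in the TGFβ response between the lines. No gene counted by size in each line separately went in opposite directions. Most genes called for the average TGFβ response had a smaller response in the Vp16-TRF1ΔN line. Those calls favour genes with alike responses, because a difference between the lines counts as noise in the fit. Il11 rose from 0.651 to 166 CPM in the TRF1ΔN line and from 0.255 to 17.2 CPM in the Vp16-TRF1ΔN line, a difference of log2 responses of -2.06 (95% counting interval -3.04 to -1.08). The difference was -1.59 for Snai1 (-2.37 to -0.81), -0.51 for Smad7 (-0.62 to -0.40), -0.30 for Fn1 (-0.37 to -0.24) and -0.22 for Zeb1 (-0.33 to -0.11). Cdh1 fell less in the Vp16-TRF1ΔN line (0.62, 0.55 to 0.68), as did Id1 (0.45, 0.33 to 0.58). For Cdh2 (0.08, 0.00 to 0.17), Zeb2 (-0.07, -0.21 to 0.06) and Snai2 (-0.51, -1.12 to 0.11) the intervals reached or nearly reached 0. With 4 libraries in 4 groups no test of this difference is possible, and the intervals cover counting error alone.

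By the size rule 202 genes had a response at least 2-fold more positive in the Vp16-TRF1ΔN line and 102 one at least 2-fold more negative. The 5 highest at a mean of 5 CPM or more were Dio3 (3.84), Akr1c19 (3.28), Ranbp3l (2.69), Mettl7b (2.66) and AW112010 (2.48), all of which were lower after TGFβ in both lines; Dio3 and Ranbp3l had a single count in the treated TRF1ΔN library, and their intervals of 1.47 to 6.20 and 0.30 to 5.08 are wide. Akr1c19 went from 230 to 2.28 CPM in the TRF1ΔN line and from 275 to 27.0 CPM in the Vp16-TRF1ΔN line. The 5 lowest at that level of expression were Has2 (-2.90), Il11 (-2.06), the tumour necrosis factor receptor family gene Relt (-1.75), the ligand gene Wnt9a (-1.69) and the small RNA gene Rny3 (-1.64). Among the 6246 genes called for the average TGFβ response with a mean of at least 1 CPM, 4112 (65.8%) had the smaller response in the Vp16-TRF1ΔN line. The difference signed by the direction of the response had a median of -0.08 and quartiles of -0.26 and 0.05. It was larger among genes changed at least 2-fold: 884 risers had median responses of 1.75 in the TRF1ΔN line and 1.51 in the Vp16-TRF1ΔN line, and 1156 fallers of -1.73 and -1.53.

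**Figure D3:**
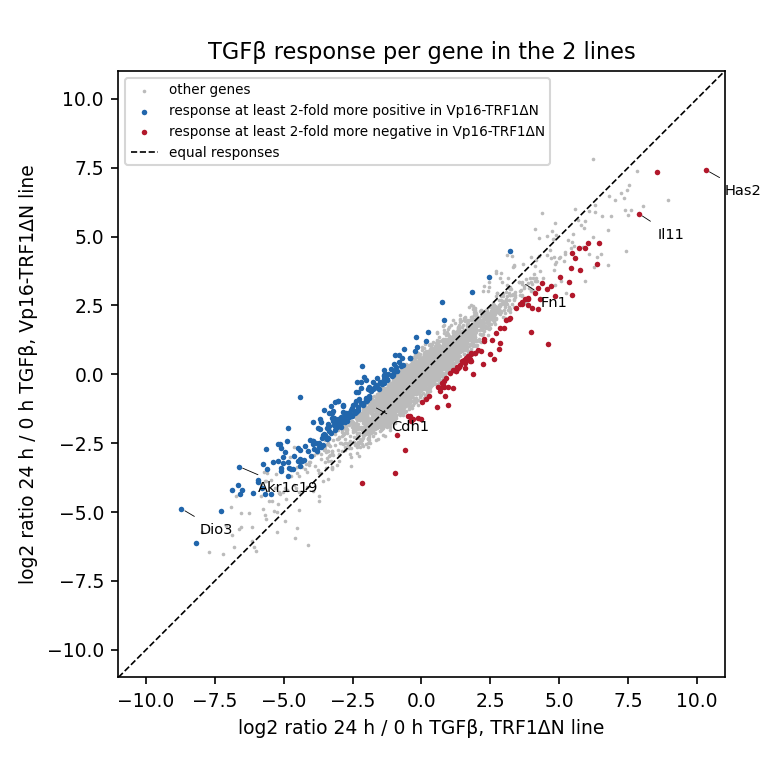
log2 ratio of 24 h over 0 h of TGFβ per gene in the TRF1ΔN line (x axis) and in the Vp16-TRF1ΔN line (y axis) for genes with a mean of at least 1 CPM; the dashed line marks equal responses, and colours mark the 202 and 102 genes counted as more positive and more negative in the Vp16-TRF1ΔN line. Most coloured points at either end lie nearer to 0 on the y axis than on the x axis.

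By list, the difference of responses was below 0 for targets of TGFβ and SMAD signalling (median -0.40, below all 10000 random lists, 27 of 33 below 0), for EMT transcription factors (-0.19, percentile 0.04) and for actin and contractile genes (-0.15, percentile 0.01, bootstrap interval -0.30 to 0.00), where Ccn2 stood at -1.28 and Lmo7 at 0.86. It was also below 0, within the middle 95% of random lists, for mesenchymal and matrix genes (-0.05, percentile 7.41), in which Pdgfrb (36 counts against 217 at 24 h) and Mmp9 (48 against 194) stood opposite Col6a2 (1.24) and Col6a1 (0.88). The median was 0.14 for epithelial and junction genes (percentile 99.8, bootstrap interval -0.03 to 0.54), of which 18 lay above 0 and 10 below, among them Krt7 at -1.30, Crb3 at 1.33 and Krt19 at 1.63. It was above 0 for the 9 BMP and Id targets (0.45, percentile 99.96), with Hey1 at 1.57 and Id2 at 1.28. Inflammatory NF-κB targets had a median of 0.32, above all random lists, led by Tnfaip2 (1.496) and the chemokine gene Cxcl5 (1.37), and interferon response genes one of 0.21 (percentile 99.9).

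Proliferation genes fell further in the Vp16-TRF1ΔN line than in the TRF1ΔN line, whereas 788 (68.2%) of the 1156 genes that fell at least 2-fold had the smaller response there. The median response of proliferation genes was -1.29 in the TRF1ΔN line and -1.68 in the Vp16-TRF1ΔN line, and the median difference of -0.35 lay below all random lists. It was led by the mitotic genes Cenpa (-1.14) and Cenpe (-0.79), while Ccne2 (0.56) and Cdc6 (0.27), which act at the start of DNA replication, stood above 0. All 40 genes were counted as at least 2-fold lower after TGFβ in the Vp16-TRF1ΔN line and 30 in the TRF1ΔN line. The other lists lay between percentiles 2.07 and 98.5 of the random lists. Across genes the difference of responses had a Spearman's rho of -0.118 with GC content, on which the random lists were not matched.

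**Figure D4:**
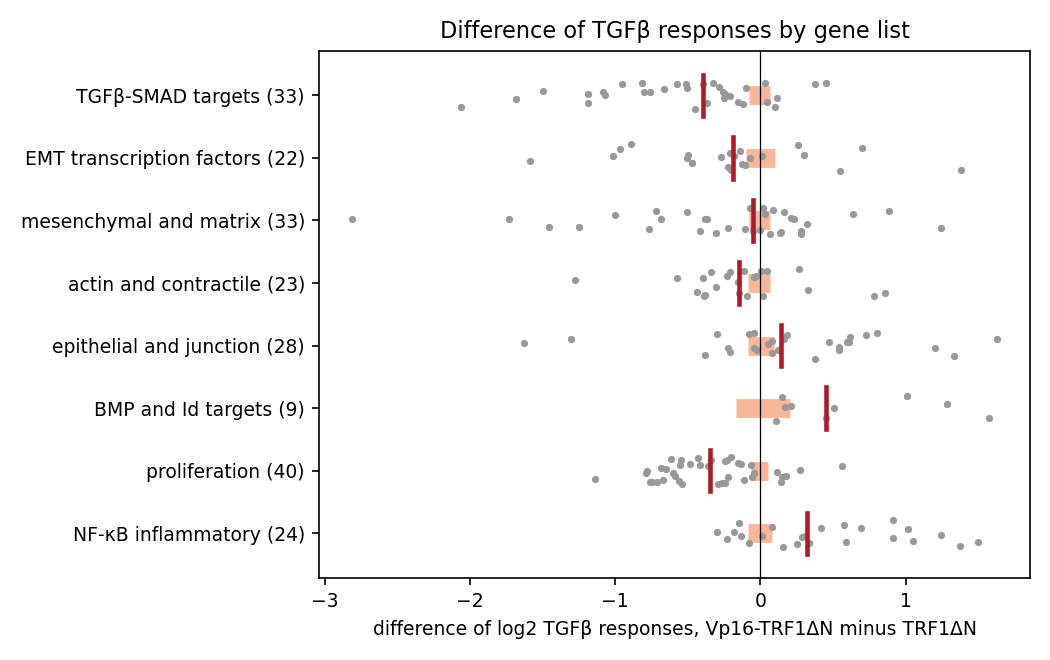
Difference of log2 TGFβ responses (Vp16-TRF1ΔN minus TRF1ΔN) for each measured member of 8 lists (grey points, number of genes in brackets), with the list's median (red bar) and the range of the middle 95% of medians of 10000 random lists matched on expression (orange band). The medians run from -0.40 for TGFβ-SMAD targets to 0.45 for BMP and Id targets.

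Because TRF1 binds telomeric repeats, the genes nearest to the distal chromosome ends were compared between the lines. The 130 measured genes within 1 Mb of the last annotated gene's end had a median line ratio of 0.02 on the log2 scale, at percentile 92.8 of random lists, and none passed the line test. At the alternative distances, the 62 genes within 0.5 Mb had a median of 0.07, at percentile 99.4, and the 658 within 5 Mb one of 0.00, at percentile 84.7. Genes near an end are neighbours, whereas random lists are drawn gene by gene, so these percentiles may overstate how unusual a list is. The genes highest within 0.5 Mb were Tpcn2 (0.65; GRCm38 chromosome 7, positions 145186524 to 145284011) and Bicd1 (0.64; chromosome 6, positions 149408886 to 149563329).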

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

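For the weaker response, the tests on scaling, on mixed RNA and on the TRF1DN level were chosen after the result was seen, as were all tests on TRF1DN RNA. Thinning to equal depth was also chosen after seeing the data.

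Several genes had TGFβ ratios on opposite sides of 1 in the 2 lines, with counting intervals that excluded 1 in both. Only the genes named and the list examples were searched, some of them picked for a large difference of responses. The intervals cover counting error only, so where a ratio is near 1 opposite directions are not established. This holds for Rrm2b in both lines, Col6a1 in the TRF1ΔN line and Bnip3 in the Vp16-TRF1ΔN line. The difference was not tested, since each group had 1 library. The type VI collagen genes Col6a1 (log2 ratio -0.18 in the TRF1ΔN line, 0.70 in the Vp16-TRF1ΔN line, difference 0.884) and Col6a2 (-0.81 and 0.43, difference 1.244) were lower in the first and higher in the second. So were Hey1, a transcriptional repressor downstream of Notch and BMP (-0.65 and 0.92, difference 1.572), the mitophagy gene Bnip3 (-0.46 and 0.23, difference 0.6898) and the ribonucleotide reductase gene Rrm2b (-0.24 and 0.16, difference 0.4028). The Y RNA gene Rny3 was higher in the first and lower in the second (1.14 and -0.49, difference -1.637). The median of the inflammatory NF-κB targets was -0.17 in the TRF1ΔN line and 0.08 in the Vp16-TRF1ΔN line, with a median difference of 0.3202. Both medians had bootstrap intervals that include 0 (-1.35 to 0.40 and -0.39 to 0.25) and lay within the range of random lists (percentiles 10.5 and 78.8), so opposite directions are not established for this list.

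The TGFβ response was smaller in the Vp16-TRF1ΔN line for 65.8% of 6246 called genes. A shift in library scaling would move risers and fallers the same way, but the median difference was -0.27 among genes that rose at least 2-fold and 0.2732 (0.232 to 0.311) among those that fell, so scaling is argued against. Depth and GC content are argued against as the whole cause, since the median signed difference was -0.08526 after thinning to equal depth and -0.08197 with the GC trend removed. Untreated RNA mixed into the treated library would weaken the response of proliferation genes too, yet these fell further in that line (-0.3498, bootstrap interval over genes -0.551 to -0.228). This cannot exclude mixing, because the response of these genes without it may not be alike in the lines. The level of TRF1DN RNA was 13.7-fold lower in the Vp16-TRF1ΔN line at 0 h (11.4 to 16.6). That level and the presence of the Vp16 domain cannot be told apart, because the lines differ in both. A difference between the cultures themselves, or in how 1 of them was treated, cannot be told apart from these either, since each group had 1 library. A biological effect of TERRA stays open and untested.

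TRF1DN RNA was 4.74-fold higher after TGFβ in the TRF1ΔN line. Reads of the endogenous gene are argued against, since Terf1 had a ratio of 0.7645 in the same pair, and scaling is argued against, since Vec_part2 had a ratio of 1.244, although Vec_part1 was 3.04-fold higher (2.71 to 3.40). A candidate explanation is transcription of the construct that responds to TGFβ: TRF1DN was also higher after TGFβ in the Vp16-TRF1ΔN line, by 1.626-fold (1.28 to 2.07). VP16 was higher there too (2.26-fold, 1.16 to 4.58), while the vector transcripts were not detectably higher in that line (Vec_part1 1.30, 0.773 to 2.18, and Vec_part2 0.986, 0.948 to 1.03), and what those cover is not given in the sources used here.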

How the results depend on the processing

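Leaving out mitochondrially encoded genes and thinning to equal depth were chosen after seeing the data. No called value changed sign under the alternatives run, but without a filter on low counts the balance of genes counted between lines at 24 h turned from mostly higher to mostly lower.

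The TGFβ response averaged over the lines had 4910 to 7509 genes called over the alternatives, against 6936. For the line average, where edgeR called 0 genes, no filter on low counts gave 109 (28 higher, 81 lower), DESeq2's Wald test 47 (13 higher, 34 lower) and leaving out mitochondrially encoded genes 4, all lower; the cause was not tested.

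Without a filter on low counts more genes enter, and the counts by size rose: 3823 for TGFβ in the TRF1ΔN line (1879 higher, 1944 lower), 2973 in the Vp16-TRF1ΔN line (1368 higher), 385 between lines at 0 h (179 higher, 206 lower), 900 at 24 h (417 higher, 483 lower) and 473 for the difference of responses (197 lower).

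With a mean of at least 5 CPM fewer genes enter: 529 were higher with TGFβ in the Vp16-TRF1ΔN line, 18 differed between lines at 0 h (3 higher, 15 lower), 198 at 24 h (141 higher, 57 lower) and 160 in the difference of responses (115 higher, 45 lower). The correlation across genes was then 0.957 between the TGFβ responses and 0.490 between the line differences (0.949 and 0.443 at 1 CPM), and the median signed difference of responses -0.0765. Within 0.5 Mb of chromosome ends the median line ratio was 0.071 over 62 genes, against 0.02 over 130 genes within 1 Mb.

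The other 115 values for whole comparisons stayed within 1.5 times the count or within the interval. Among genes and lists, 977 values stayed, 367 moved, 14 passed and 3 no longer passed the test. The 14 were line differences under DESeq2's Wald test, led by Alpl, and the 3 TGFβ responses there were Terf1 (adjusted p = 0.0877), Dab2 (0.191) and Insig1 (0.308). Leaving out a library leaves no residual degree of freedom, so the value equals that of 1 pair, with no test. Repeats inside chromosomes, and their alternatives, were not run, since the genome sequence was not used.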

Other observations

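The test on distance from chromosome ends was chosen after the values that fix its outcome had been tabulated, and the genes in the next paragraph were chosen after their values were seen.

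The protease inhibitor-like gene Wfdc2 and Pdzrn3 lie just under the mean of 5 CPM set for naming genes. Their log2 ratios of Vp16-TRF1ΔN over TRF1ΔN at 0 h and 24 h were -4.31 and -3.28 for Wfdc2 and -3.38 and -3.08 for Pdzrn3. DESeq2's Wald test called both for the line average and edgeR called neither, except Pdzrn3 with mitochondrially encoded genes left out (adjusted p = 0.0455).

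Genes within 0.5 Mb of distal chromosome ends had a median line ratio of 0.07, with 41 of 62 above 0. A part played by 1 chromosome was examined by leaving out each in turn. With random lists drawn anew the percentile was 99.3, and the lowest value was 96.66, without the 5 genes of chromosome 6. Taking the lowest of these values builds in some fall, so it does not decide whether 1 chromosome plays a part. GC content and distance from the end cannot be told apart: lists matched on GC content as well put the median at percentile 97.33, and the excess of 0.08642 (0.00847 to 0.214) over genes between 0.5 and 1 Mb restates the pattern and lends distance no support. None of these genes passed the line test (edgeR), in which 1779 of all genes passed before adjustment and DESeq2's Wald test called 47.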
